A study of Ogataea parapolymorpha with 8 samples.

How the data were processed

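Bioreactor cultures of Ogataea parapolymorpha gave 8 libraries in 4 groups of 2: wild type in chemostats labelled micro-aerobic and aerobic, and a mutant labelled as deleted for GUT2 and NDI/NDE genes in aerobic batch and aerobic chemostat. Per the labels' protocols, cells were frozen in liquid nitrogen, RNA was extracted with acidic phenol and chloroform, and polyadenylated RNA was made into libraries with a stranded TruSeq kit. Groups were taken from the labels alone. The series text names 2 biological replicates without saying more of the cultures, so p-values measure the spread between these samples.

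The authors deposited a table of counts of read pairs per gene, with no normalization. Per the file headers, counting was done with featureCounts on gene features of the annotation, over read pairs with both ends mapped and not chimeric, and without a strand setting, so reads of overlapping genes cannot be told apart. The submitters' processing notes name Bowtie 1.2.1.1, SAMtools 1.3.1, featureCounts 1.6.0 and edgeR 3.28.1. The genome build is not given in the sources used here beyond the strain name DL-1 of the deposited annotation, which was made with funannotate and whose coordinates are printed. The authors also deposited 5 tables over 5268 genes with log2 fold changes, average log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value. Their model, normalization and adjustment are not given in the sources used here. The count table holds 4 more columns of other libraries, which were not used here.

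The table lists 5428 genes. No counts fell on 62 of them, 42 of which are tRNA genes, and the 25 genes on mitochondrial DNA had 0 or 1 count per library. In all, 303 genes overlap another gene. A name stands in the annotation for 859 genes, a homolog in Saccharomyces cerevisiae for 3250, and a locus tag for 5019, all of which matched the RefSeq table of the assembly Hansenula_2, used for names only. Homologs were turned into symbols with a table of 635 symbols written from general knowledge. Of 201 that could be compared with a name in the annotation 190 were the same and 11 differed, and the homolog's symbol was then used, as for ENO2, BAT2 and GSY2 (ENO1, BAT1 and GSY1 in the annotation). A symbol is that of the closest homolog the annotation gives, and for families of paralogs it does not settle which member the gene is.

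Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (5265 genes), libraries were scaled by TMM (factors 0.859 to 1.12), and all 8 libraries were fitted together with a mean per group. Changes were tested two-sided with the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.118 with 4 residual degrees of freedom, and by group it ran from 0.0488 in the mutant batch to 0.157 in the mutant chemostat. CPM use the TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the 31 lists with at least 3 measured members. The list of type II NADH dehydrogenases had 1 measured member, NDE1, and was not tested.

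The groups, the first 3 comparisons, the tests, the gene lists by symbol, the rule for named genes and the alternatives listed below were fixed before the data were examined. Named genes were the targeted genes, the 5 largest rises and falls per comparison among named genes with an adjusted p below 0.05, at least 10 CPM in a group and values that do not overlap between groups, and up to 4 members of each list with the largest change (or 1 to 2 with the smallest p where none passed). Members without a symbol were added to 5 lists by protein domains and gene ontology terms after the counts had been seen, without use of any change: 85 of 94 members of the cytosolic ribosomal proteins, 50 of 73 of the mitochondrial ribosomal proteins, 12 of 12 of complex I, 17 of 20 of sugar transport and 3 of 8 of methanol metabolism. REI1, ARX1, SIS1, PPE1 and OXA1 came in by that step and are not ribosomal proteins. PCD1, OPAR_001650 and the genes of the closing section given by number were chosen after their values were seen, as was the comparison of the mutant chemostat with the libraries labelled micro-aerobic.

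The 10 genes with most counts took 7.967% to 12.641% of a library. The first 2 principal components held 57.5% and 26.6% of the variance and separated the 4 groups. Replicates differed by more than sampling noise, with chi-square per degree of freedom of 5.15 in the batch, 6.75 in the libraries labelled micro-aerobic, 24.8 in those labelled aerobic and 38.3 in the mutant chemostat. A gene with no count in a group was set against a floor of 3 counts over that group. Intervals (95%) and floors cover counting error only. Data were simulated with 1 mean and 1 dispersion per gene for all groups and 100 genes above a minimum CPM changed at each size. In the 4 comparisons in the order of the report, the test recovered 94%, 97%, 95% and 96% of genes changed by log2 1. It recovered 100% of those changed by log2 2, and called 15, 15, 8 and 12 unchanged genes of 5055, 5052, 5052 and 5052. The unequal spread of the groups and the large share of genes called were not simulated, so error rates in the real data may differ.

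Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, no filter and a filter of 5 CPM in 2 libraries, a fit of the 4 compared libraries alone, thinning to the smallest library, a test against a fold of 1.5 (glmTreat), leaving out each library, a term for the run number in the mutant titles, camera with an estimated correlation and fry. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.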

Results

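The polyadenylated RNA of bioreactor cultures of Ogataea parapolymorpha, a thermotolerant yeast that can grow on methanol, was sequenced in 8 libraries, 2 in each of 4 groups. The wild type, strain CBS11895, came from chemostats at a dilution rate of 0.1 per h and pH 6 with urea, Tween 80 (a source of oleic acid) and 10 mg/L ergosterol. The labels name an antifoam, pluronic acid, for the wild-type cultures only. One wild-type group was labelled micro-aerobic and received 20 g/L glucose and 420 mg/L Tween 80, and the other was labelled aerobic and received 7.5 g/L glucose and 84 mg/L Tween 80. The mutant, strain IMX2167, is labelled as deleted for GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase, and for NDI and NDE genes, which code for type II NADH dehydrogenases of mitochondria in yeasts. It was grown with air and 7.5 g/L glucose, either in batch at pH 6 or in a chemostat at 0.1 per h and pH 5.

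The libraries labelled micro-aerobic held 6190556 and 6319424 counts in genes, and those labelled aerobic 6104949 and 6749184. The mutant libraries were deeper, with 8731655 and 11126081 counts in batch and 9549284 and 10087942 in the chemostat. A floor of 3 counts corresponded to 0.270 to 0.491 CPM (counts scaled by library size) of a single library total. Levels below are CPM as mean ± SD over the n = 2 libraries of a group. Changes are log2 ratios ± SE, with the SE taken as the absolute change over the square root of the quasi-likelihood F value. For genes with few counts in a group, such as NDE1 with 11 in the mutant chemostat, this SE can lie below counting error. "Rose" and "fell" are used of genes with an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

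The targeted genes were examined first. GUT2 (OPAR_001648, Chr_03, 740390 to 742327, plus strand, 1 exon) stood at 349 ± 12.7 in the libraries labelled micro-aerobic and 387 ± 8.16 in those labelled aerobic, against 103 ± 11.4 in the mutant batch and 28.6 ± 1.76 in the mutant chemostat. NDE1 (OPAR_004935, Chr_07, 732835 to 734477, plus strand), the 1 gene that could be named as a type II NADH dehydrogenase, stood at 53.7 ± 5.71 and 69.2 ± 4.07 in the same wild-type groups, 4.95 ± 0.561 in the batch and 0.511 ± 0.0273 in the chemostat. Between mutant chemostat and labelled aerobic wild type, GUT2 fell by 3.76 ± 0.15 (adjusted p = 1.2e-10) and NDE1 fell by 7.04 ± 0.28 (adjusted p = 1.3e-10). Within the mutant, GUT2 was higher in batch than in the chemostat by 1.85 ± 0.14 and NDE1 by 3.23 ± 0.34. Neither gene passed the test between the wild-type groups, where the changes were -0.15 and -0.37 (adjusted p = 0.362 and 0.0997).

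**Figure D1:**
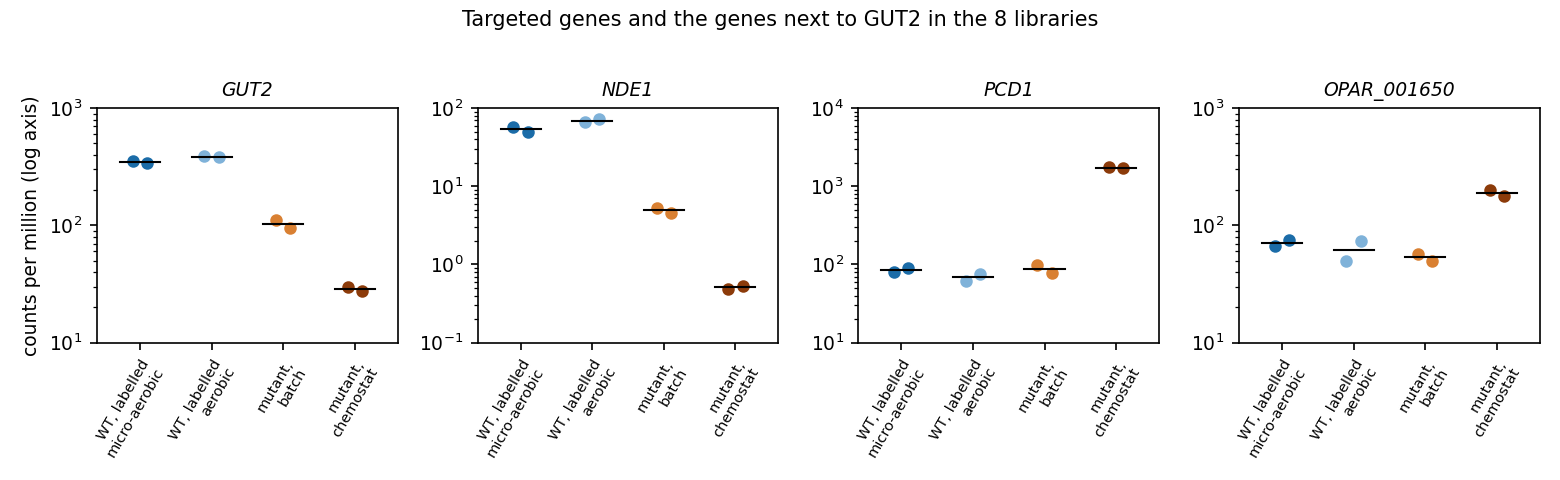
CPM on a log axis of GUT2, NDE1 and the neighbours PCD1 and OPAR_001650 in the 4 groups; points are libraries (2 per group) and bars are group means. GUT2 and NDE1 are lower in both mutant groups than in both wild-type groups, and PCD1 and OPAR_001650 are highest in the mutant chemostat.

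The first comparison asks how the wild type's transcripts differ between limited and ample oxygen, taken as the libraries labelled micro-aerobic minus those labelled aerobic. In the libraries labelled micro-aerobic, genes of the TCA cycle, the glyoxylate cycle, fatty acid degradation and methanol metabolism were higher, and genes of glycolysis and sterol synthesis were lower. None of these list calls held with an estimated correlation (adjusted p = 0.143 to 0.186). Here and below, that setting also tests on the 4 residual degrees of freedom, so such a loss does not show correlation alone at work. ICL1 (isocitrate lyase, OPAR_000168) rose by 8.38 ± 0.29, from 2.29 ± 1.89 to 728 ± 77.4, and FDH1 (formate dehydrogenase, OPAR_005301) by 6.20 ± 0.21, from 63.7 ± 6.27 to 4706 ± 245. ERG25 (sterol C-4 methyl oxidase, OPAR_004641) fell by 7.92 ± 0.18, from 3631 ± 65.4 to 15.0 ± 0.689. Of 5265 genes tested, 1222 were higher and 1176 lower, and 471 and 414 of them by at least 2-fold.

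Other genes with a symbol at the top of the rises were YAT1 (carnitine acetyltransferase, 7.24 ± 0.27), IDP2 (cytosolic NADP-dependent isocitrate dehydrogenase, 6.66 ± 0.19) and ACS1 (acetyl-CoA synthetase, 5.47 ± 0.18, from 269 ± 23.5 to 11948 ± 794). At the top of the falls stood VHT1 (biotin transporter, -7.55 ± 0.40), YHK8 (-6.99 ± 0.26) and JLP1 (sulfonate dioxygenase, -6.62 ± 0.21). ADH7, an alcohol dehydrogenase, had 3 counts over the libraries labelled micro-aerobic and 728 over those labelled aerobic, a ratio of 263 with a counting interval of 89.5 to 1276.

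All 12 measured glycolysis genes were lower (median change -2.08, camera adjusted p = 5.9e-09, adjusted p = 0.143 with an estimated correlation). HXK2 (hexokinase) fell from 1856 ± 348 to 178 ± 18.2, GLK1/EMI2 (glucokinase) fell by 3.01 ± 0.15 and PFK1 (phosphofructokinase) by 2.59 ± 0.18. In the TCA cycle and pyruvate dehydrogenase list 15 of 18 genes rose and none fell (median 1.80, adjusted p = 2.2e-08, adjusted p = 0.186 with an estimated correlation). CIT1 (citrate synthase) went from 176 ± 0.281 to 7249 ± 321, ACO1 (aconitase) rose by 3.33 ± 0.15 and SDH2 (succinate dehydrogenase) by 3.27 ± 0.17. The 4 glyoxylate cycle and gluconeogenesis genes rose (median 4.40, adjusted p = 1.6e-04, adjusted p = 0.143 with an estimated correlation). MLS1 (malate synthase) rose by 4.59 ± 0.15 and PCK1 (phosphoenolpyruvate carboxykinase) by 4.22 ± 0.20.

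In beta-oxidation 10 of 13 genes rose and 1 fell (median 1.48, adjusted p = 3.4e-05, adjusted p = 0.143 with an estimated correlation). After YAT1 came the carnitine carrier gene CRC1 (5.40 ± 0.20), YAT2 (3.37 ± 0.20) and CTA1 (peroxisomal catalase, from 617 ± 0.928 to 5213 ± 249). All 8 methanol metabolism genes rose (median 3.97, or 2.75 with the gene at 0 set to its bound; adjusted p = 4.3e-07, adjusted p = 0.148 with an estimated correlation). OPAR_002900, which carries alcohol oxidase domains, stood at 6708 ± 15.0 against 116 ± 13.5. OPAR_000368, a gene with transketolase domains, was at 0 in both libraries labelled aerobic and at least 4.62-fold higher in those labelled micro-aerobic, against 3 counts over the group. In sugar transport 16 of 20 genes rose and 3 fell (median 2.0, adjusted p = 2.5e-06, adjusted p = 0.143 with an estimated correlation). Among these transporter genes OPAR_002811 went from 6.75 ± 0.167 to 3948 ± 337 and OPAR_002328 from 21.5 ± 14.8 to 5104 ± 283.

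Sterol synthesis held 16 falls and 1 rise among 24 genes (median -0.90, adjusted p = 5.9e-07, adjusted p = 0.143 with an estimated correlation). ERG11 (lanosterol demethylase) fell from 11783 ± 881 to 292 ± 1.12, ERG3 (sterol desaturase) by 4.34 ± 0.16 and ERG1 (squalene epoxidase) by 4.02 ± 0.17. Among the respiratory chain lists, 10 of 12 complex I genes rose (11 adjusted over the list alone; median 1.16, adjusted p = 6.9e-05, adjusted p = 0.179 with an estimated correlation). OPAR_004897 rose by 1.32 ± 0.15. In ATP synthase 7 of 13 genes rose (median 0.79, adjusted p = 0.0126, adjusted p = 0.634 with an estimated correlation), ATP4 by 1.07 ± 0.16. In the pentose phosphate pathway 6 of 7 genes rose and 1 fell (median 0.89, adjusted p = 0.0279, adjusted p = 0.256 with an estimated correlation). ZWF1 (glucose-6-phosphate dehydrogenase) rose by 1.32 ± 0.14. Of 92 genes listed as cytosolic ribosomal proteins 38 fell and 3 rose (median -0.34, adjusted p = 9.4e-04, adjusted p = 0.682 with an estimated correlation). RPL32 fell by 1.22 ± 0.20, and the riser REI1 (1.15 ± 0.22) codes for a factor of 60S subunit maturation, not for a ribosomal protein.

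The 20 other lists tested did not pass in this comparison, though single members changed. HEM13 (coproporphyrinogen oxidase) fell from 1148 ± 75.9 to 58.8 ± 3.45 in heme synthesis, where 3 genes rose and 5 of 9 fell (adjusted p = 0.244). MEP2 (ammonium permease) fell from 1097 ± 7.14 to 67.2 ± 12.5 in nitrogen source use, with 3 rises and 7 falls among 16 genes (adjusted p = 0.0530). In fermentation and pyruvate bypass (4 rises and 1 fall of 7, adjusted p = 0.158) ALD4 (mitochondrial aldehyde dehydrogenase) rose by 5.30 ± 0.19 and PDC5 (pyruvate decarboxylase) fell by 2.44 ± 0.19. STL1 (glycerol transporter) rose by 3.54 ± 0.20 in glycerol metabolism (3 rises and 1 fall of 6, adjusted p = 0.244), and SFC1 (succinate-fumarate carrier) by 3.14 ± 0.14 among the NADH shuttles and fumarate or orotate reduction (4 rises and 2 falls of 8, adjusted p = 0.271). SCS7 (sphingolipid hydroxylase) fell by 2.65 ± 0.15 in fatty acid synthesis and desaturation (5 rises and 2 falls of 7, adjusted p = 0.207), and PEX11 rose by 3.13 ± 0.15 among the peroxins (8 rises and 3 falls of 15, 8 and 4 adjusted over the list alone, adjusted p = 0.0944). CCP1 (cytochrome c peroxidase) rose by 1.76 ± 0.15 in oxidative stress defence (9 rises and 3 falls of 17, adjusted p = 0.0788), and FET3 (ferroxidase) fell by 1.82 ± 0.17 in iron and copper uptake (1 rise and 5 falls of 8, 1 and 6 adjusted over the list alone, adjusted p = 0.190).

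In complex III and cytochrome c 5 of 10 genes rose (adjusted p = 0.0620), and in complex IV 4 of 6 fell (adjusted p = 0.0533), COX12 by 1.01 ± 0.16. HSP26 (small heat shock protein) fell by 3.71 ± 0.29 among heat shock and chaperone genes (8 rises and 6 falls of 18, adjusted p = 0.925), and ATH1 (trehalase) rose by 1.93 ± 0.22 in trehalose and glycogen (3 rises and 5 falls of 12, adjusted p = 0.590). Counts of rises and falls were 13 and 16 of 57 in amino acid synthesis (13 and 17 adjusted over the list alone, adjusted p = 0.640; 15 and 11 under upper quartile scaling) and 4 and 5 of 16 in mating and meiosis (adjusted p = 0.925). The medians of these 4 lists lay between -0.08 and 0.02 and changed sign with the scaling, and in 3 of them, trehalose and glycogen excepted, the median, the mean and camera's direction differed in sign. Ribosome biogenesis held 5 rises and 12 falls of 73 (4 and 4 adjusted over the list alone, adjusted p = 0.851; median 0.07, with camera's direction down; 6 rises and 4 falls under upper quartile scaling), and mitochondrial ribosomal proteins 14 and 10 of 73 (14 and 9 adjusted over the list alone, adjusted p = 0.848). Autophagy held 2 rises and 2 falls of 20 (2 and 1 adjusted over the list alone, adjusted p = 0.584), thiamine synthesis 3 and 1 of 8 (adjusted p = 0.244), and cell cycle and histones 3 and 1 of 16 (2 and 1 adjusted over the list alone, adjusted p = 0.748). ATG1 (autophagy kinase) fell by 1.93 ± 0.15, THI4 (thiazole synthase) rose by 1.02 ± 0.15 and CDC20 fell by 1.58 ± 0.25. Where rises and falls are printed without a count adjusted over the list alone, here and in the comparisons that follow, that count equalled the one over all genes. Lists with no printed rises and falls are not covered by this.

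Glucose, Tween 80 and the oxygen label differed together between these groups, so the comparison does not separate them. The library titles also carry a different code for each group, whose meaning is not stated, so separate experiments cannot be told from the condition. The directions rest on the labels as given, and an exchange of the 2 labels would turn every one of them. The libraries labelled micro-aerobic lay nearer to the mutant aerobic chemostat than those labelled aerobic (root mean square log2 distances 0.568 and 1.199). Without replicate 1 of the libraries labelled micro-aerobic the test called 1593 genes, 823 higher and 770 lower. Cytosolic ribosomal proteins lost their call as a list without aerobic replicate 1 (adjusted p = 0.169), and ATP synthase (0.149) and the pentose phosphate pathway (0.0707) without aerobic replicate 2. The balance of rises and falls depended on the scaling, with 1427 genes higher and 966 lower under upper quartile and 1166 and 1252 under RLE scaling.

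**Figure D2:**
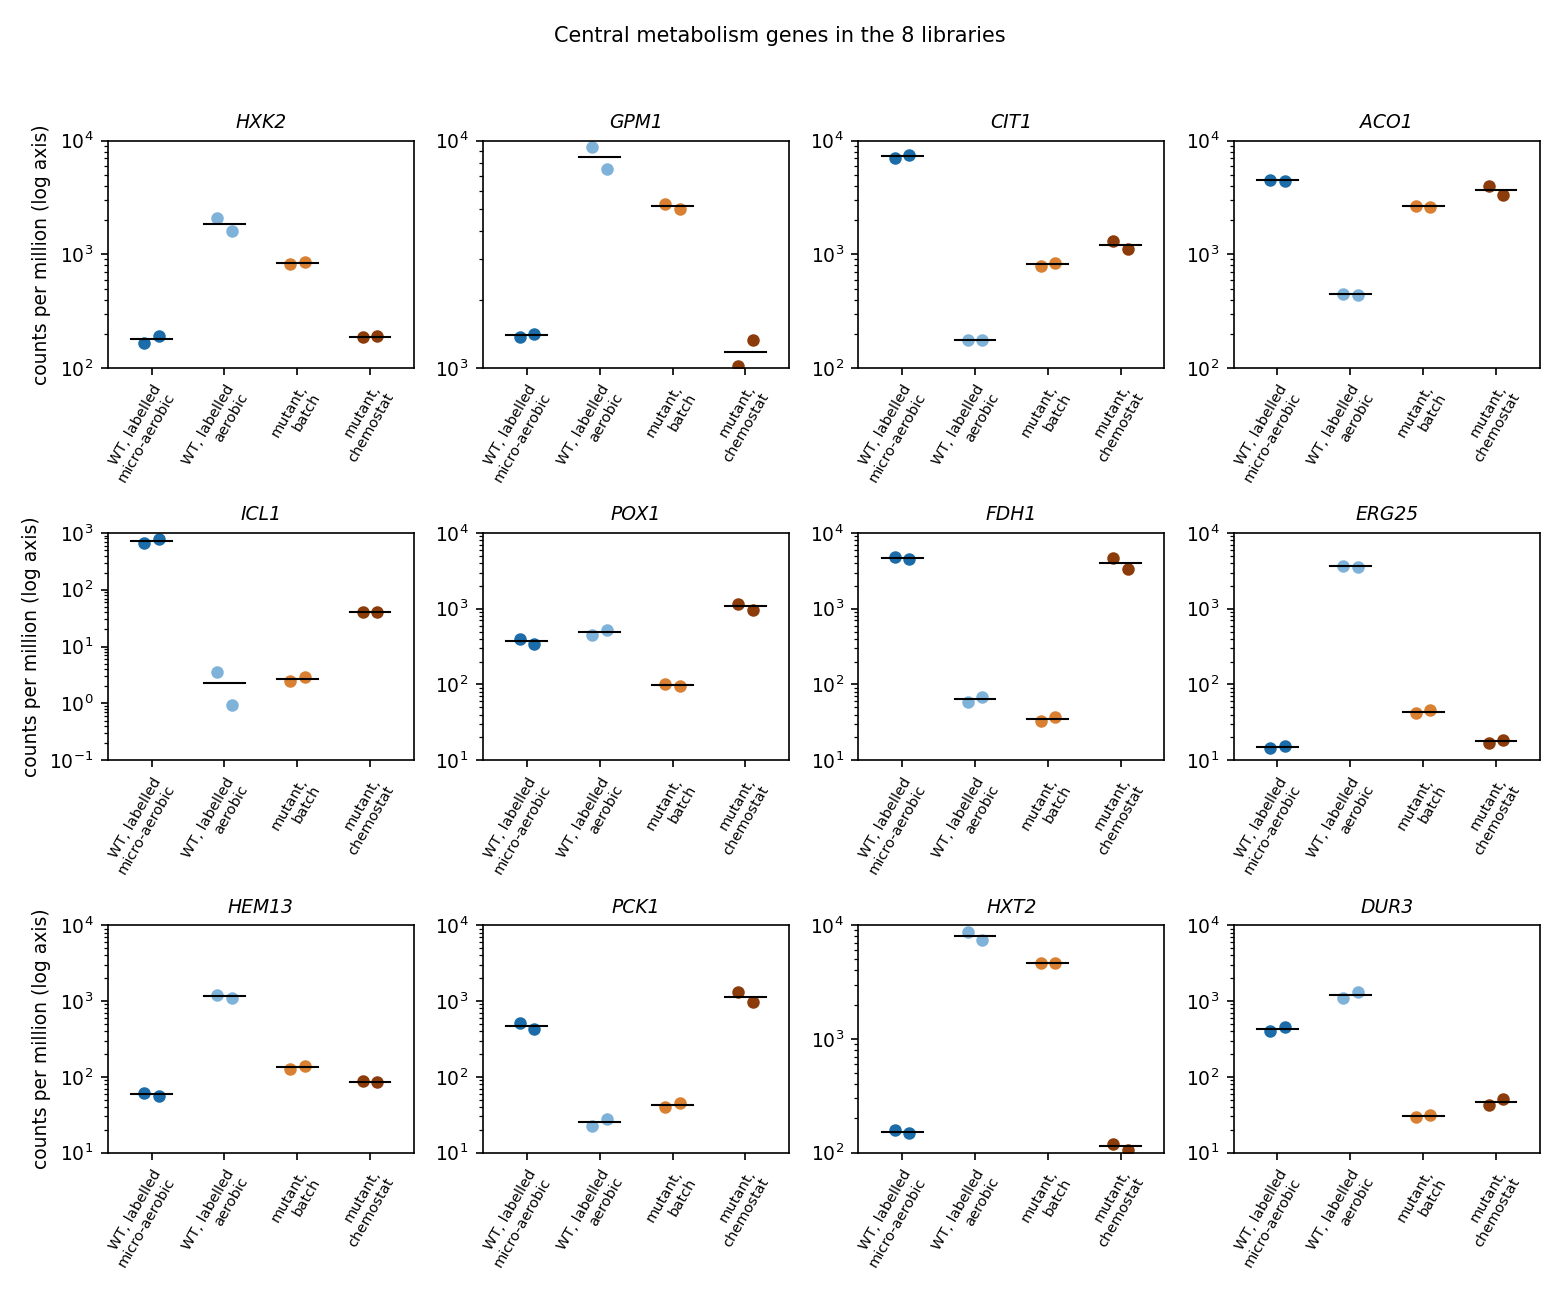
CPM on a log axis of 12 genes of central metabolism, sterol and heme synthesis and transport in the 4 groups; points are libraries (2 per group) and bars are group means. ERG25 stands at 3631 in the libraries labelled aerobic and at 15.0 in those labelled micro-aerobic, while ICL1 goes from 2.29 to 728.

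The second comparison asks how the mutant's transcripts differ between batch growth and growth at a set dilution rate, taken as aerobic batch minus aerobic chemostat. In batch, genes of ribosomes, amino acid synthesis and glycolysis were higher, and genes of beta-oxidation, methanol metabolism, complex I and most sugar transporters were lower. None of these list calls held with an estimated correlation (adjusted p = 0.0963 to 0.399). HXT2 (hexose transporter, OPAR_001509) rose by 5.36 ± 0.18, from 113 ± 9.71 to 4661 ± 15.1, while FDH1 fell from 4005 ± 901 to 35.4 ± 2.99 and OPAR_002328 (sugar transporter domains) from 7908 ± 632 to 6.24 ± 3.04. Of 5265 genes 1292 were higher and 1412 lower, 365 and 546 of them by at least 2-fold.

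The rises were led among genes with a symbol by ADH7 (7.01 ± 0.39, from 0.231 ± 0.0485 to 31.9 ± 2.09) and HXT2, followed by DOG1 (2-deoxyglucose-6-phosphate phosphatase, 4.19 ± 0.18), YHK8 (3.61 ± 0.23) and VHT1 (3.27 ± 0.35). DERI1 (D-erythrulose-4-phosphate isomerase, OPAR_000630) was at 0 in both batch libraries and at least 184-fold lower there than in the chemostat. RGI2 (-8.64 ± 0.22), IDP2 (-7.69 ± 0.20) and MPH2/MPH3 (maltose permease, -6.83 ± 0.24) fell as well. DOG1 and RGI2 overlap other genes, and without strand in the counting their reads cannot be told from those of the neighbour.

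Of the 92 genes listed as cytosolic ribosomal proteins 82 rose and 2 fell (83 and 2 adjusted over the list alone; median 0.94, adjusted p = 1.3e-15, adjusted p = 0.399 with an estimated correlation). RPS22A went from 443 ± 75.6 to 1506 ± 156 and RPS7A rose by 1.37 ± 0.21, and ARX1 (1.41 ± 0.13), also in this list, codes for a nuclear export factor of the 60S subunit. Ribosome biogenesis held 49 rises and no fall among 73 genes (50 rises adjusted over the list alone; median 0.65, adjusted p = 1.2e-10, adjusted p = 0.0973 with an estimated correlation). RRP12 rose by 1.41 ± 0.14 and RPA135, a subunit of RNA polymerase I, by 1.33 ± 0.14. Among mitochondrial ribosomal proteins 55 of 73 rose and 2 fell (58 and 2 adjusted over the list alone; median 0.68, adjusted p = 1.2e-10, adjusted p = 0.252 with an estimated correlation), MRPL44 by 1.41 ± 0.16. In amino acid synthesis 49 of 57 genes rose and 1 fell (50 and 1 adjusted over the list alone; median 0.89, adjusted p = 7.7e-15, adjusted p = 0.127 with an estimated correlation). HIS5 (histidinol-phosphate aminotransferase) rose from 39.6 ± 0.178 to 291 ± 2.53, BAT2 (branched-chain aminotransferase) by 2.58 ± 0.16, ARG8 by 2.28 ± 0.14 and THR4 (threonine synthase) by 2.01 ± 0.14.

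All 12 glycolysis genes rose (median 1.63, adjusted p = 2.9e-08, adjusted p = 0.134 with an estimated correlation). CDC19 (pyruvate kinase) went from 1138 ± 49.1 to 5198 ± 116 and HXK2 rose by 2.15 ± 0.16. Sugar transport held 15 falls and 2 rises among 20 genes (16 and 2 adjusted over the list alone; median -2.48, adjusted p = 2.8e-08, adjusted p = 0.0963 with an estimated correlation). The falls included OPAR_002811 (-9.23 ± 0.24) and OPAR_000631 (-8.53 ± 0.24). The 4 glyoxylate cycle and gluconeogenesis genes fell (median -3.22, adjusted p = 3.7e-04, adjusted p = 0.134 with an estimated correlation), PCK1 from 1142 ± 242 to 42.8 ± 4.00 and ICL1 fell by 3.87 ± 0.26. Fermentation and pyruvate bypass did not pass as a list (2 rises and 4 falls of 7). Among its members ALD4 fell by 4.58 ± 0.18 and ACS1 by 3.14 ± 0.16, whereas ACS2 rose by 2.25 ± 0.15.

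All 13 beta-oxidation genes fell (median -2.08, adjusted p = 2.4e-09, adjusted p = 0.0973 with an estimated correlation). Among them were POX1 (acyl-CoA oxidase, from 1069 ± 133 to 99.1 ± 3.50) and FOX2 (-3.27 ± 0.16). In methanol metabolism 7 of 8 genes fell and 1 rose (median -1.92, adjusted p = 1.9e-04, adjusted p = 0.240 with an estimated correlation). OPAR_002900 went from 6405 ± 825 to 50.6 ± 1.59. Of 15 peroxin genes 12 fell (median -0.80, adjusted p = 3.0e-04, adjusted p = 0.134 with an estimated correlation), PEX11 by 3.16 ± 0.15. All 12 complex I genes fell (median -1.2, adjusted p = 4.4e-06, adjusted p = 0.134 with an estimated correlation), ALI1 by 1.72 ± 0.14. Of 10 genes of complex III and cytochrome c, by contrast, 7 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.56, adjusted p = 0.0301, adjusted p = 0.556 with an estimated correlation). CYC1 (cytochrome c) rose from 676 ± 61.2 to 2373 ± 179. Autophagy held 13 falls among 20 genes (median -0.57, adjusted p = 0.00377, adjusted p = 0.421 with an estimated correlation), ATG8 by 1.54 ± 0.19. Cell cycle and histones held 8 falls and 1 rise among 16 (median -0.43, adjusted p = 0.0425, adjusted p = 0.345 with an estimated correlation). The cyclin genes PCL1 (-1.64 ± 0.20) and CLN3 (-0.96 ± 0.19) fell.

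The other 17 lists did not pass. In the TCA cycle and pyruvate dehydrogenase list 8 genes rose and 6 of 18 fell (adjusted p = 0.378). Sterol synthesis held 10 rises and 1 fall of 24 (8 and 1 adjusted over the list alone, adjusted p = 0.0971), ERG25 up by 1.31 ± 0.15. AAT1 (aspartate aminotransferase) rose by 2.90 ± 0.14 and SFC1 fell by 1.95 ± 0.14 among the NADH shuttles and fumarate or orotate reduction (2 rises and 2 falls of 8, adjusted p = 0.787). TSA1 (peroxiredoxin) rose by 2.59 ± 0.18 in oxidative stress defence (6 rises and 5 falls of 17, 6 and 6 adjusted over the list alone, adjusted p = 0.843), whose median of -0.01 changed sign with the scaling. STL1 fell by 3.95 ± 0.19, GDH1 (glutamate dehydrogenase) rose by 1.68 ± 0.15, HSP12 fell by 2.28 ± 0.22 and GPH1 (glycogen phosphorylase) fell by 1.94 ± 0.16, each in a list that did not pass. In fatty acid synthesis and desaturation (adjusted p = 0.843) the median was -0.04 while camera's direction was up.

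Growth mode and pH (6 in batch, 5 in the chemostat) differed together here. The growth rate in batch and the glucose left in either culture are not given in the labels, so their part cannot be separated. Without replicate 1 of the batch the test called 1745 genes, 870 higher and 875 lower. The call of cell cycle and histones was lost without batch replicate 1, batch replicate 2 or chemostat replicate 2 and with the run number as a block (adjusted p = 0.0534 to 0.113), and that of complex III without chemostat replicate 2 (0.152).

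The third comparison sets the mutant chemostat against the wild-type libraries labelled aerobic. Apart from the targeted genes, TCA cycle, beta-oxidation, methanol and sugar transport genes were higher in the mutant than in these libraries, and glycolysis and sterol synthesis genes were lower. No list call here held with an estimated correlation (adjusted p = 0.143 to 0.244 for these lists). Against the libraries labelled micro-aerobic, of these lists only sugar transport passed (adjusted p = 0.0189, adjusted p = 0.653 with an estimated correlation), and no list did without mutant chemostat replicate 2. PHO89 (sodium-phosphate cotransporter, OPAR_003569) fell by 11.68 ± 0.29, from 1880 ± 177 to 0.541 ± 0.486, and ERG25 fell by 7.67 ± 0.18. IDP2 rose by 6.46 ± 0.19 to 1169 ± 126 and PCK1 by 5.49 ± 0.21 to 1142 ± 242. Of 5265 genes 1648 were higher and 1547 lower, 783 and 541 of them by at least 2-fold. These groups had the largest coefficients of variation (0.157 and 0.153), which the main fit pools with those of the other groups. A fit of the 4 compared libraries alone called 2682 genes, 1393 higher and 1289 lower.

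DERI1, at 0 in both libraries labelled aerobic, was at least 105-fold higher in the mutant chemostat, and FDH1 (5.97 ± 0.21), MPH2/MPH3 (5.67 ± 0.22) and YAT1 (5.62 ± 0.25) rose. ADH7 fell by 7.99 ± 0.38. DUR3 (urea transporter, from 1194 ± 159 to 46.5 ± 5.71) and DUR32 (-7.00 ± 0.35, overlapping another gene) fell, as did DUR12 (urea amidolyase, -2.34 ± 0.18), while GLT1 (glutamate synthase) rose by 2.31 ± 0.17. In the libraries labelled micro-aerobic, which also received urea, DUR32 stood at 0.798 ± 0.226, DUR3 at 427 ± 29.1 and DUR12 at 364 ± 61.9. The level of DUR32 thus did not follow the named nitrogen source alone. Nitrogen source use did not pass as a list, with 4 rises and 5 falls of 16 (adjusted p = 0.517).

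All 12 glycolysis genes were lower in the mutant chemostat (median -2.01, adjusted p = 2.9e-07, adjusted p = 0.188 with an estimated correlation), HXK2 by -3.30 ± 0.16 and ENO2 (enolase) by -2.31 ± 0.16. The TCA cycle and pyruvate dehydrogenase list held 15 rises and no fall among 18 genes (median 1.40, adjusted p = 3.9e-06, adjusted p = 0.244 with an estimated correlation). They included SDH2 (3.37 ± 0.17) and FUM1 (fumarase, 3.06 ± 0.16). All 13 beta-oxidation genes rose (median 1.76, adjusted p = 1.9e-06, adjusted p = 0.143 with an estimated correlation). Among them were FOX2 (2.94 ± 0.16) and POT1 (3-ketoacyl-CoA thiolase, 2.93 ± 0.19). All 8 methanol metabolism genes rose (median 3.47, or 2.76 with the gene at 0 set to its bound; adjusted p = 7.5e-06, adjusted p = 0.188 with an estimated correlation). The 4 glyoxylate cycle and gluconeogenesis genes rose (median 3.41, adjusted p = 0.00192, adjusted p = 0.188 with an estimated correlation). Sugar transport held 16 rises and 2 falls among 20 genes (median 1.96, adjusted p = 3.9e-06, adjusted p = 0.143 with an estimated correlation), OPAR_000609 going from 4.62 ± 0.605 to 2232 ± 321.

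In sterol synthesis 19 of 24 genes fell and 2 rose (median -0.78, adjusted p = 7.5e-06, adjusted p = 0.143 with an estimated correlation), ERG11 by -5.58 ± 0.17 and NCP1 (cytochrome P450 reductase) by -3.29 ± 0.13. All 12 complex I genes rose (median 1.07, adjusted p = 3.9e-05, adjusted p = 0.188 with an estimated correlation), ALI1 by 1.74 ± 0.14. ATP synthase held 10 rises and 1 fall among 13 genes (10 and 2 adjusted over the list alone; median 0.90, adjusted p = 0.0301, adjusted p = 0.675 with an estimated correlation). Complex IV held 5 falls among 6 (median -0.74, adjusted p = 0.0331, adjusted p = 0.675 with an estimated correlation), COX6 by -1.04 ± 0.17. The pentose phosphate pathway held 6 rises and 1 fall among 7 (median 1.26, adjusted p = 0.0266, adjusted p = 0.244 with an estimated correlation). Iron and copper uptake held 5 falls and 1 rise among 8 (1 rise and 6 falls adjusted over the list alone; median -0.87, adjusted p = 0.0331, adjusted p = 0.244 with an estimated correlation), FRE4 (ferric reductase) from 350 ± 109 to 10.3 ± 1.73. Of the 92 genes listed as cytosolic ribosomal proteins 55 fell and 5 rose (median -0.56, adjusted p = 3.8e-05, adjusted p = 0.675 with an estimated correlation), RPS7A by -1.48 ± 0.21. SIS1 (-1.17 ± 0.16), in the same list, codes for a co-chaperone that binds ribosomes.

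The other 18 lists did not pass, with amino acid synthesis at 13 rises and 27 falls of 57 (13 and 28 adjusted over the list alone, adjusted p = 0.0644). Mitochondrial ribosomal proteins held 19 rises and 26 falls of 73 (adjusted p = 0.435), and the members PPE1 (-1.26 ± 0.15) and OXA1 (1.23 ± 0.18, overlapping another gene) code for a methylesterase and a membrane insertase. Ribosome biogenesis held 16 rises and 17 falls of 73 (12 and 16 adjusted over the list alone, adjusted p = 0.517). AAT1 (-2.99 ± 0.14), HEM13 (-3.73 ± 0.14), HSP26 (-4.68 ± 0.30) and OLE1 (fatty acid desaturase, -1.57 ± 0.14) fell, and ATH1 rose by 2.95 ± 0.22, each in a list that did not pass. The median and camera's direction differed in sign in fermentation and pyruvate bypass (-0.08 against up) and in trehalose and glycogen (0.11 against down). In mating and meiosis the median was 0.22 and the mean -0.13, and in fatty acid synthesis and desaturation the median was 0.13 and the mean -0.16. The medians of fermentation, nitrogen source use, ribosome biogenesis, mitochondrial ribosomal proteins and heat shock genes changed sign with the scaling. Under upper quartile scaling ribosome biogenesis held 21 rises and 10 falls and mitochondrial ribosomal proteins 20 and 14, and under RLE scaling ribosome biogenesis held 12 and 20.

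**Figure D3:**
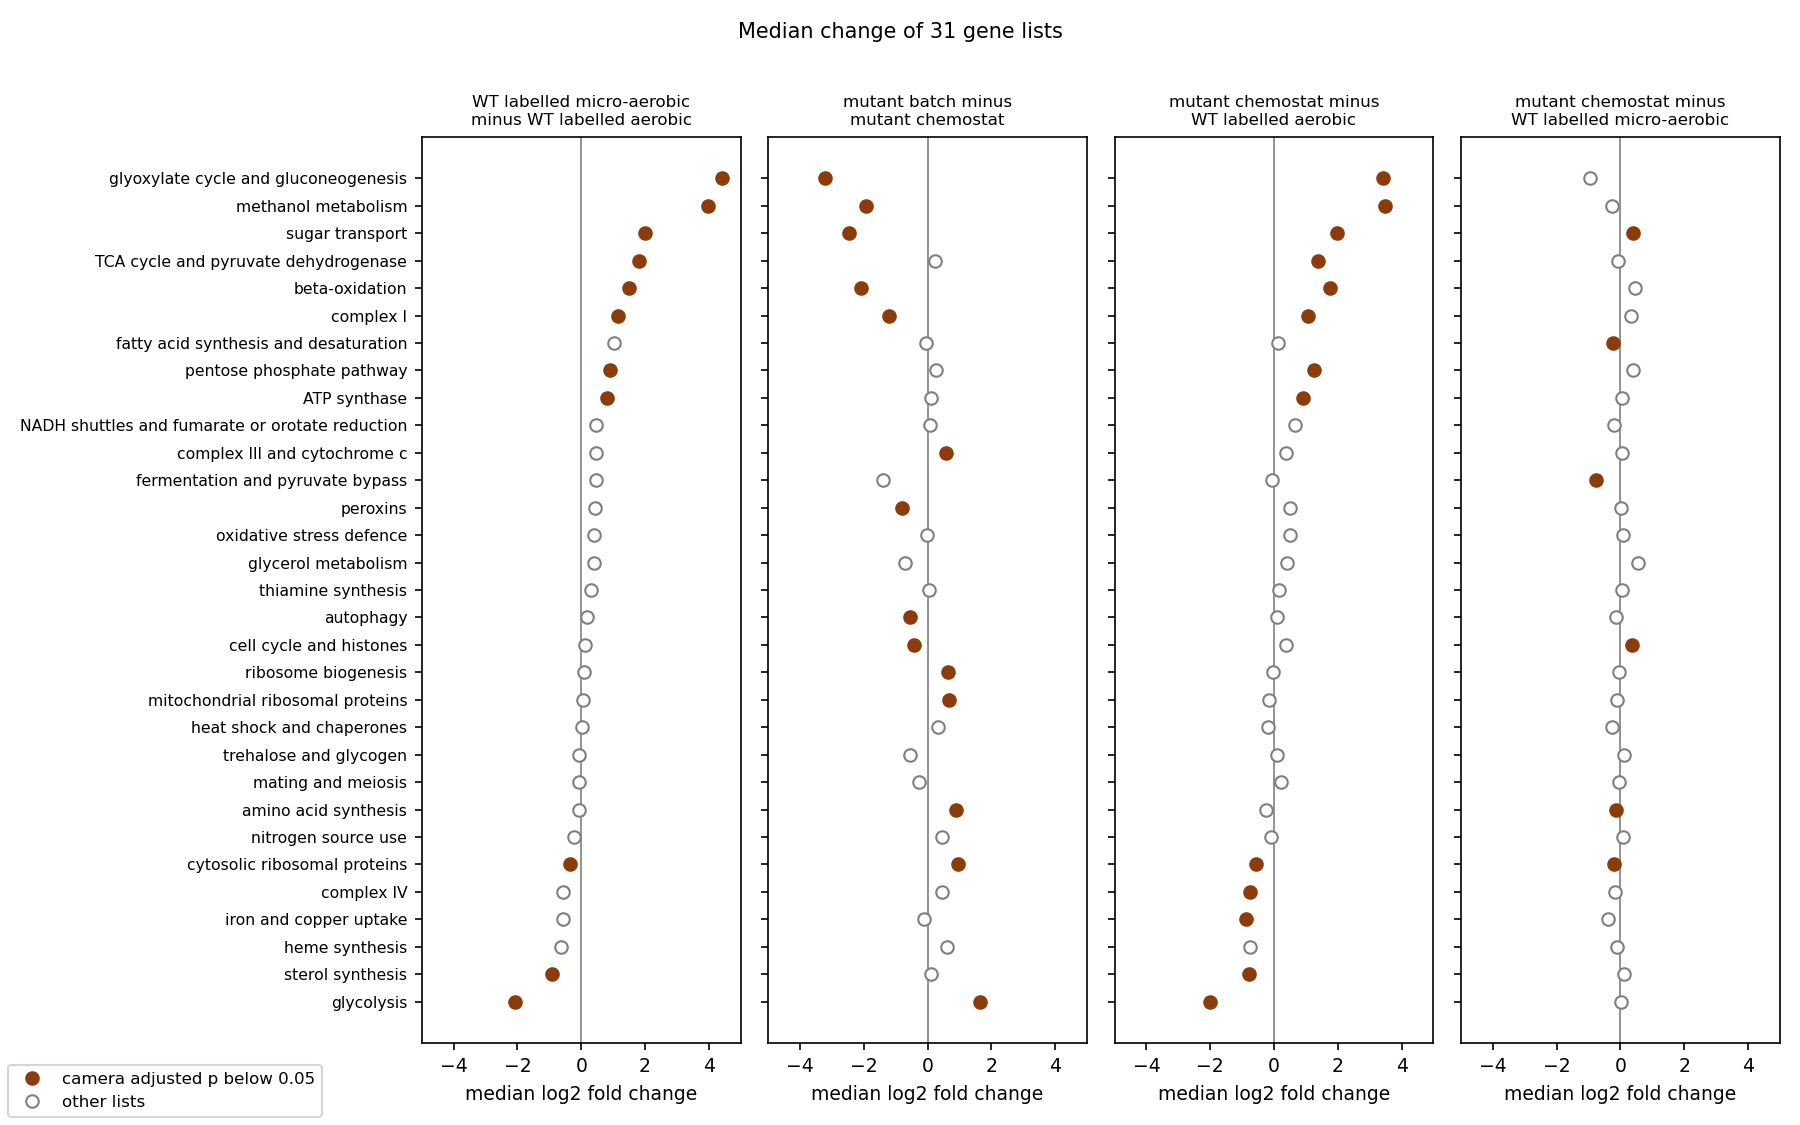
Median log2 change of the 31 gene lists in 4 comparisons, with filled points where camera's adjusted p was below 0.05 at a preset correlation. Glycolysis lies at -2.08 in the wild-type comparison and at 1.63 in the comparison of mutant batch with mutant chemostat.

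Strain, pH (5 against 6), the nitrogen source named in the medium and the additions of Tween 80, ergosterol and antifoam differed together in this comparison. The library titles also differ in prefix between the strains. If the wild-type labels were exchanged, oxygen would differ here as well. Under upper quartile scaling, which moved the median of all genes by 0.178, 2057 genes were higher and 1180 lower, or 63.5% higher against 51.6% by the main scaling. Calls lost without a library were those of complex IV (adjusted p = 0.0556 and 0.0724), ATP synthase (0.0508 and 0.111) and iron and copper uptake (0.0854).

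The mutant chemostat was also set against the wild-type libraries labelled micro-aerobic, a comparison chosen after the data were seen. In it strain, pH, glucose, the nitrogen source named in the medium, Tween 80, ergosterol, antifoam and the oxygen label differ together. Here 722 genes were higher and 703 lower in the mutant, 164 and 100 of them by at least 2-fold, and GUT2 fell by 3.61 ± 0.15 and NDE1 fell by 6.67 ± 0.28. PCD1 (a NUDIX family phosphatase, OPAR_001649) rose by 4.35 ± 0.17, from 85.4 ± 8.19 to 1738 ± 38.2, UGA4 (a GABA permease) by 4.03 ± 0.30, MEP2 by 3.99 ± 0.17, DERI1 by 3.24 ± 0.30 and MAE1 (malic enzyme) by 2.38 ± 0.14. PHO89 (-8.66 ± 0.29), CRC1 (-4.27 ± 0.18), ICL1 (-4.16 ± 0.21), FRE4 (-4.15 ± 0.23) and DUR3 (-3.20 ± 0.16) were lower in the mutant.

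In this comparison 6 of 31 lists passed. Glycolysis held 3 rises and 1 fall among 12 genes (median 0.01, adjusted p = 0.983), and the TCA cycle list 2 falls among 18 (median -0.07, adjusted p = 0.261). Sterol synthesis held 3 rises and 3 falls among 24 (median 0.10, adjusted p = 0.983), and methanol metabolism 2 falls among 8 (median -0.25, adjusted p = 0.274). Beta-oxidation held 7 rises and 5 falls among 13 (median 0.45, adjusted p = 0.474). Fatty acid synthesis and desaturation held 3 falls among 7 genes, with OLE1 down by 1.11 ± 0.14, and amino acid synthesis 13 falls and 1 rise among 57, with ARG1 down by 1.16 ± 0.15. Sugar transport held 7 rises and 2 falls among 20 genes, and cell cycle and histones 6 rises among 16 (7 adjusted over the list alone), with PCL1 up by 1.31 ± 0.20. These 4 lists had a camera adjusted p = 0.0189, and an adjusted p = 0.653 with an estimated correlation. Fermentation and pyruvate bypass held 5 falls and 2 rises among 7 (adjusted p = 0.0323, adjusted p = 0.653 with an estimated correlation), ACS2 by -2.29 ± 0.15. The list of cytosolic ribosomal proteins held 14 falls and 2 rises among 92 (7 and 1 adjusted over the list alone; adjusted p = 0.0347, adjusted p = 0.955 with an estimated correlation). The median and the mean of glycerol metabolism were 0.54 and -0.26, those of oxidative stress defence 0.08 and -0.03, and the peroxins had a median of 0.01 with camera's direction down, none of which passed. The medians of the TCA cycle, ribosome biogenesis and mating and meiosis lists changed sign with the scaling. The number of genes called depended on single libraries: it was 670 without micro-aerobic replicate 1, 280 without micro-aerobic replicate 2 and 440 without mutant chemostat replicate 1, and the lists numbered 11 without mutant chemostat replicate 1 and 0 without replicate 2. Under upper quartile scaling 943 genes were higher and 492 lower (65.7% against 50.7% higher).

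The wild-type comparison and the mutant's batch comparison share no library. Of the genes called in both, 646 were higher in the libraries labelled micro-aerobic and lower in the mutant batch, and 487 the reverse, against 327.7 and 288.6 for independent lists. Genes that moved the same way numbered 135 higher in both and 164 lower in both, against 299.9 and 315.4. ICL1, FDH1, PCK1 and OPAR_002328 belonged to the first kind, and HXK2, GPM1 and ERG25 to the second. Across the 5265 genes the changes correlated at r = -0.507 and rho = -0.412, and genes are not independent replicates. The genes that moved in opposite directions numbered 735 without micro-aerobic replicate 1. Those that moved the same way numbered 194 without micro-aerobic replicate 2, 174 without batch replicate 1 and 180 without batch replicate 2.

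The labels do not say which groups the authors' 5 tables of fold changes compare. Each was set against all group pairs by its correlation across genes with differences of group means. The authors' deposited table closest to the wild-type comparison (r = 0.979, with its sign reversed) called 2711 genes at an adjusted p below 0.05, including 2395 of the 2398 called here, in the same direction. The authors' deposited table closest to the batch comparison (r = 0.994, sign reversed) called 3052, including 2698 of 2703. The authors' deposited table closest to the mutant chemostat against the libraries labelled micro-aerobic (r = 0.988, sign reversed) called 1943, including 1422 of 1425. The other 2 of the authors' deposited tables, with 4200 and 4217 genes called, correlated with no pair of the 4 groups above 0.437 and 0.311.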

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

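The comparison with the libraries labelled micro-aerobic as second wild type, the crossed run numbers, the orders of columns in fry and the upper quartile medians of the lists were tests chosen after the data were seen; the others were planned. No called gene or list turned its direction. The calls of GUT2 and NDE1 in the mutant chemostat held under every alternative. Of the named genes' results under alternatives, counted per gene and alternative, 67 of 1713 in the wild-type comparison, 66 of 1928 in the batch comparison, 21 of 1677 between mutant chemostat and labelled aerobic wild type, and 205 of 1387 with the other wild-type group lost their call, and 2, 0, 1 and 1 gained one. Counted per gene in the same order, 31 of 143, 27 of 138, 12 of 140 and 64 of 116 named genes lost or gained a call under some alternative.

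In the order of the report's 4 comparisons, a test against a fold of 1.5 (glmTreat), which asks for more than any change, called 956, 995, 1514 and 177 genes. With an estimated correlation camera called 0 lists in each of the 4. That setting also takes its p-values from the 4 residual degrees of freedom, while the preset one takes them from the number of genes. The calls therefore rest on the preset setting, and their loss cannot be put on the correlation between genes alone. The test fry, which does not set a list against other genes, called 22 (16 up, 6 down), 23 (12 up, 11 down), 23 (14 up, 9 down) and 8 (3 up, 5 down) lists. It kept 10 of 11, 14 of 14, 12 of 13 and 4 of 6 of camera's calls. Cytosolic ribosomal proteins lost theirs in all but the batch comparison (adjusted p = 0.178, 0.0603 and 0.579), and amino acid synthesis with the other wild-type group (0.0502). Over the 24 orders of the design's columns the batch count went from 22 to 23, as heat shock and chaperones went from an adjusted p of 0.0466 to 0.0536, and the count with the other wild-type group from 8 to 10. DESeq2 called 2400, 2649, 3160 and 1507 genes, and a fit of the 4 compared libraries alone called 2277, 2685, 2682 and 1182. Of genes changed in both the wild-type and the batch comparison, 323 moved in opposite directions and 42 in the same direction when a change of at least 2-fold was asked in both.

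Leaving out a library left 1 library in a group, assumed to vary like the other groups. The wild-type comparison then called 1593 (without micro-aerobic replicate 1) to 2448 genes and 10 to 13 lists, the batch comparison 1745 (without batch replicate 1) to 2789 genes and 13 to 14 lists, and the mutant chemostat against the libraries labelled aerobic 2757 to 3304 genes and 10 to 15 lists. Of the lists called with all libraries, at least 9 of 11, 12 of 14 and 10 of 13 were kept. With the other wild-type group the range was 280 (without micro-aerobic replicate 2) to 2105 genes, with 670 without micro-aerobic replicate 1 and 440 without mutant chemostat replicate 1, and 0 (without mutant chemostat replicate 2) to 11 lists (without its replicate 1). Shared calls in opposite directions ranged from 735 (without micro-aerobic replicate 1) to 1254, and those in the same direction from 174 (without batch replicate 1) to 351, with 194 without micro-aerobic replicate 2 and 180 without batch replicate 2. The cause of these losses beyond the smaller number of libraries was not tested.

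The mutant libraries share run numbers in their titles, and it is not stated whether same-numbered libraries are paired. Their deviations from the group means correlated at -0.245 across genes. With 2 libraries per group this cannot decide whether they are paired. With the run number as a replicate block the batch comparison called 2569 genes and 13 lists, with 1098 and 279 shared calls. With crossed numbers it called 2806 genes and 14 lists. Thinning to the smallest library, which shows what depth limits, left 2365, 2591, 3116 and 1301 genes.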

Other observations

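All genes in this part were singled out, and all of its tests chosen, after the results had been seen. A stretch of 4 neighbouring genes on Chr_02 was high in the mutant chemostat. OPAR_000628 (29569 to 32096, minus strand, glycoside hydrolase domains) stood at 4623 ± 1370 CPM (SD, n = 2) there, 1646 ± 93.9 in the wild-type libraries labelled micro-aerobic, 1.67 ± 0.600 in the mutant batch and 0 in both libraries labelled aerobic, which makes it at least 17647-fold and 6353-fold higher in the first and second group than in the last. OPAR_000629 (32829 to 34640, minus strand, dihydroxyacetone kinase domains) stood at 128 ± 10.7 in the mutant chemostat, with 2 counts over the libraries labelled aerobic (ratio 740, counting interval 205 to 6113). DERI1 (34888 to 35379, plus strand) stood at 27.4 ± 1.67 in the mutant chemostat and 2.87 ± 0.228 in the libraries labelled micro-aerobic, and had no count in the other groups. OPAR_000631 (35781 to 37397, plus strand, sugar transporter domains) stood at 902 ± 184 in the mutant chemostat, 187 ± 23.0 in the libraries labelled micro-aerobic, 3.15 ± 0.665 in those labelled aerobic and 2.42 ± 0.0441 in the batch.

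A second stretch of Chr_02 had counts almost only in the libraries labelled aerobic. OPAR_001177 (952273 to 953613, plus strand, oxidoreductase domain) stood at 347 ± 68.3 there and at 0.718 ± 0.564 or less elsewhere. OPAR_001178 (953848 to 955374, plus strand, transporter domains) and OPAR_001179 (955823 to 957364, plus strand, flavin monooxygenase domains) stood at 6.29 ± 2.43 and 525 ± 2.32, and were at 0 in the libraries labelled micro-aerobic, at least 25.6-fold and 2195-fold lower. OPAR_001195 (987093 to 988349, plus strand, FAD-binding oxidoreductase domains) stood at 2047 ± 53.9 against 6.74 ± 0.903 to 12.1 ± 2.22 in the other groups. OPAR_001303 (Chr_03, 169092 to 170762, plus strand) carries a pyridine nucleotide-disulphide oxidoreductase domain, a fold that type II NADH dehydrogenases share with other enzymes. It stood at 627 ± 4.34 in the libraries labelled micro-aerobic, 126 ± 11.9 in those labelled aerobic, 31.4 ± 0.404 in the mutant batch and 21.5 ± 4.84 in the mutant chemostat.

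In the wild-type libraries labelled micro-aerobic, glycolysis and sterol genes were low and TCA cycle and fatty acid degradation genes high. The tables argue against the scaling between libraries, since the highest median of the glycolysis list over 3 scalings was -1.98. A candidate explanation is that the labels of the 2 wild-type groups were exchanged: the group labelled aerobic lay 2.11 times as far from the mutant aerobic chemostat as the group labelled micro-aerobic (root mean square log2 distances 1.199 and 0.568), and both libraries of each were on the same side (1.24 and 1.18 against 0.551 and 0.609). The mutant aerobic batch lay about as far from both over all genes (0.945 and 0.923), near the libraries labelled micro-aerobic in ERG25 (43.9 against 15.0 and 3631 CPM) and HEM13 (133 against 58.8 and 1148) and near those labelled aerobic in ICL1 (2.74 against 728 and 2.29). Conditions as labelled remain open, because glucose, Tween 80, medium and strain differ together, and the correlation of -0.507 with the mutant's batch change cannot be told apart from an effect of the feed.

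Reads remained on GUT2 in the mutant libraries. Wild-type cells or RNA are argued against as the sole source in the mutant chemostat. There GUT2 stood at 7.77% and NDE1 at 0.832% of the wild-type mean, a ratio of 9.34 (counting interval 5.16 to 18.7, 612 and 11 counts). In batch the shares were 27.97% and 8.04% (2060 and 99 counts), a ratio of 3.48 for which no interval was computed. The wild-type mean is also that of chemostats, and no wild-type batch library gives the levels in batch. Wild-type cells or RNA therefore remain open for the batch libraries. Reads of PCD1, whose 3' end lies 17 bases beyond that of GUT2 on the other strand, are argued against as the source in batch. There GUT2 was higher than in the chemostat by 1.85 (log2), while PCD1 was lower by 4.31. In the chemostat PCD1 stood at 1738 CPM and GUT2 at 28.6, so a small share of PCD1 reads would suffice. For the chemostat this test cannot decide. Part of the gene model may have been left in place, and the 27.97% of the wild-type mean found in batch cannot decide it, because counts per gene hold no positions.

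PCD1 (OPAR_001649, Chr_03, 742345 to 743621, minus strand) and its neighbour OPAR_001650 (743622 to 745274, minus strand, stress protein domain) were high in the mutant chemostat alone, PCD1 at 1738 ± 38.2 against 68.1 ± 9.23 to 87.4 ± 15.1 elsewhere. The strain alone, through the edit beside these genes, is argued against, since PCD1 in the mutant batch was 1.02 times the higher wild-type mean. Chemostat growth alone is argued against too, since the lowest mutant chemostat library was 18.8 times the highest wild-type library. Strain and condition together, or pH 5, may account for the pattern and cannot be told apart, because no other group has that strain in a chemostat or that pH, and OPAR_001650 was 3.55 times as high in the mutant chemostat as in the mutant batch.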
